A study of Homo sapiens with 6 samples.

How the data were processed

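Total RNA of MDA-MB-231 cells grown in DMEM with fetal bovine serum was extracted with a column kit, treated with DNase and checked on a Bioanalyser, per the labels' protocols. Biotin-labelled RNA of 6 samples was hybridised to Illumina HumanHT-12 v4 BeadChips, 3 with a scrambled shRNA and 3 with 1 hairpin against SOX4. The submitters' processing notes name GenomeStudio 2011.1.

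The authors deposited 3 kinds of values. The first is a table of probe intensity on a linear scale, neither background-subtracted nor normalized, with a deposited detection p-value of each probe on each array in the column beside its intensity. The second is a table of log2 values with 1 row per gene symbol, which the authors made by RMA in ArrayStar, per the file headers of the third table. Its column medians run from 2.80 to 2.82, and its differences between the groups run in the direction SOX4 shRNA minus scrambled. Other details of its scaling are not given in the sources used here. The third, the authors' deposited table, holds log2 group means and a linear fold per gene, with genes under 2.5 in both means removed, per the file headers. The column of its second mean carries another hairpin's name, while a header line of the same table names the SOX4 hairpin samples. Its log2 fold correlated at 0.996 across 22259 matched genes with the SOX4 shRNA minus scrambled difference of the value table, with a median absolute difference of 0.0084. It was therefore read as the SOX4 comparison, and 16 of its names look like dates.

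A pair of columns of the intensity table carry the same heading, that of scrambled replicate 2, and none names replicate 3. Both were used as scrambled arrays without a replicate number of their own and are called 2a and 2b here. No per-sample column was left out.

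Intensities were background-corrected and normalized with neqc in limma 3.58.1 under R 4.3.3, which fits the background from the detection p-values, adds an offset of 16, quantile normalizes and takes log2. Probes with a detection p under 0.01 on at least 3 of the 6 arrays were kept, which left 15717 of 47322 probes (33.2%). The brightest kept probe stood for each gene symbol, and unnamed probes stayed as rows of their own, giving 12451 rows, of which 12069 carry a symbol. Symbols are those of the chip table, and 10352 matched the RefSeq gene table of assembly GRCh38.p14, which was used only for names and for which genes neighbour each other. Of 973 changed genes with several kept probes, 10 had probes called in opposite directions.

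Groups were compared with lmFit and eBayes with an intensity trend, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Differences are log2 of SOX4 shRNA minus scrambled. For a gene not well above background on any array of 1 group, the fold is given as a bound. The bright group's mean was set against the dim group's mean of, per array, the higher of the lowest detected signal and the probe's own signal. On the deposited scale the detection floor and the array median of 119 to 124 limit what can be seen of dim genes.

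Before the data were examined, 20 gene lists, the settings to be varied and the rule for named genes were fixed. The rule takes SOX4, SOX11, SOX12 and TRPM7, the 12 raised and 12 lowered named genes with the largest change and no overlap between groups, up to 3 raised and 3 lowered members per list, and CDH1, CDH2, VIM, FN1, SNAI2, ZEB1, EZH2 and MYH9. Other list members named in the text were chosen after their values were seen, as was a set of 20 abundant leucocyte transcripts. Lists with at least 5 measured members were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists, with fry and an estimated correlation as alternatives. The NF-kB, interferon and hypoxia calls hold with an estimated correlation. A gene can stand on more than 1 list. Single values of some list members are not reported here.

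The fit was tested on simulated data made from the real arrays with 200 genes changed by known folds. Those whose changed probe stood for the gene were counted, among 13957 genes tested. The fit called 94.9% of 59 genes changed 1.5-fold, 96.6% of 59 changed 2-fold and 100% of 57 changed 4-fold. Of its calls, 5.56% were unchanged genes. With no change simulated it called 0 genes. The changed genes were drawn from the brighter detected probes. Each probe had the same spread plus background noise, independent between genes. These rates therefore do not cover dim genes or genes that vary together.

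Alternatives were no background correction, cyclic loess, the authors' values, no detection filter, detection on all 6 arrays, the mean of a gene's probes, every kept probe, no intensity trend, the replicate number as a block, and leaving out each array in turn. The slide as a block was not run because the files used here name no slides. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.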

Results

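Expression was measured on Illumina HumanHT-12 v4 BeadChips in MDA-MB-231 cells, a human breast cancer line of mesenchymal, triple-negative type. The cells had been transduced either with a scrambled short hairpin RNA (shRNA), the control, or with an shRNA against SOX4, a transcription factor of the SOX family. Each group had 3 arrays. The series title places SOX4 downstream of the ion channel TRPM7 in the maintenance of the mesenchymal phenotype, so the comparison asks what changes in these cells when SOX4 is depleted. The labels do not say whether the 3 samples of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Between 15197 and 16187 of the 47322 probes were detected per array, and the number of arrays limits the precision. Across genes, which are not independent replicates, the lowest correlation between arrays of a group was 0.995 and the highest between arrays of different groups was 0.983.

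The SOX4 transcript level was lower on every SOX4 shRNA array than on every scrambled array. Its single probe, ILMN_1815745, had a mean normalized log2 signal of 7.89 ± 0.16 (SD, n = 3) with the scrambled hairpin and 5.46 ± 0.27 (SD, n = 3) with the SOX4 hairpin. The log2 difference was -2.43 ± 0.14 (SE), or 5.37-fold lower, with an adjusted p of 4.1e-13 in limma. In deposited intensity the group means were 328 ± 34 and 146 ± 9.3 (SD, n = 3). Without background correction the difference was -1.23, and it was -3.22 in the authors' values. The probe was above background on 2 of the 3 SOX4 shRNA arrays. The relatives of SOX4 gave no measurable comparison: neither probe of SOX11 was above background on any array, and the SOX12 probe was above it on 1 scrambled array only. The TRPM7 probe was not above background on any of the 6 arrays, so its level could not be compared.

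**Figure D1:**
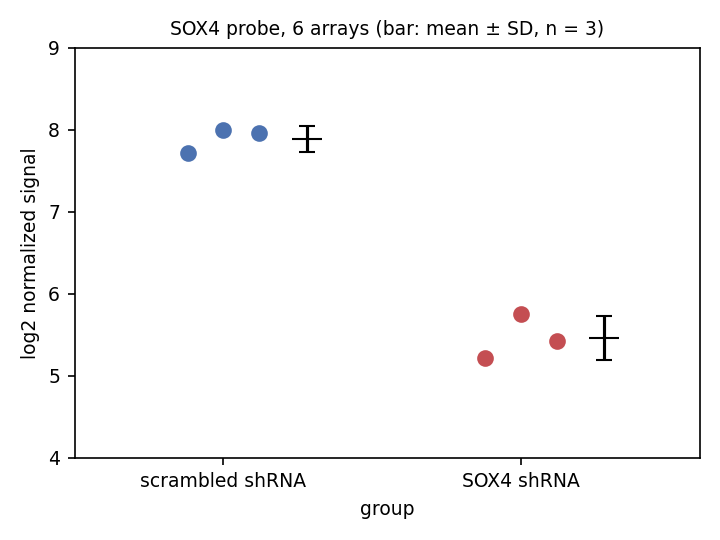
Normalized log2 signal of the SOX4 probe (vertical axis, which starts at 4) on each of the 3 scrambled shRNA and 3 SOX4 shRNA arrays; each point is 1 array and the bar beside each group is its mean ± SD. The scrambled arrays average 7.89 and the SOX4 shRNA arrays 5.46, without overlap.

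Depletion of SOX4 was accompanied by a broad change of modest size. Of 12451 genes and unnamed probes tested, 3807 changed at an adjusted p under 0.05 in limma, 1891 of them higher and 1916 lower with the SOX4 hairpin. The median size of these changes was 1.30-fold, and 280 genes had a fitted change of at least 2-fold, 162 upward and 118 downward. With genes not above background in 1 group set at their bounds, 240 reached 2-fold, 139 upward and 101 downward. The 3 SOX4 shRNA values lay wholly outside the range of the scrambled values for 5226 genes, 42.0% of those tested, where chance gives 10%. The median log2 difference over all genes was -0.01. Quantile normalization holds this median near 0 and favours like counts of raised and lowered genes, so a global shift 1 way would not show. Among the changed genes, 94 raised ones were detected on no scrambled array, and 68 lowered ones on no SOX4 shRNA array.

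The 12 most raised named genes, ranked by fitted difference, included cytokine, chemokine and acute-phase genes. Those given below as a bound have no measured rank among the named genes. LTB, a cytokine of the tumour necrosis factor family, was not above background on any scrambled array and was at least 20.9-fold higher with the SOX4 hairpin (adjusted p = 5.2e-22, limma). The defensin gene DEFB103B rose by 4.73 ± 0.09 and the acute-phase gene SAA1 by 4.59 ± 0.09 on the log2 scale (SE, n = 3 per group), from levels detected on every scrambled array. The related gene SAA2 was at least 6.0-fold higher, the cytokine IL24 at least 8.85-fold, the chemokine CXCL16 at least 4.41-fold and the adhesion molecule CEACAM1 at least 2.78-fold. MPZL2, another adhesion molecule, was above background on 1 of the 3 scrambled arrays and had a log2 difference of 3.58, which is imprecise so near the floor. The remaining genes among the 12 most raised were TNFRSF1B, a receptor for tumour necrosis factor, with a log2 difference of 2.51, the cytokine IL32 with 2.45, C15orf48 with 2.36 and the apoptosis inhibitor BIRC3 with 2.33. Several of these genes had a kept probe with a smaller log2 difference, 2.12 for SAA1, 0.76 for MPZL2, 0.95 for C15orf48 and 0.92 for BIRC3. So did LTB (2.95), IL24 (1.76) and CEACAM1 (1.38), whose fitted differences are not measured folds; their bounds rest on the brightest probe.

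SOX4 itself was among the 12 named genes that fell most. MPP4, a membrane scaffold protein gene, was at least 4.05-fold lower, the cyclin CCNA1 at least 3.47-fold, the surface glycoprotein CD24 at least 2.82-fold and C5orf46 at least 2.51-fold, which are bounds and have no rank against SOX4. The authors' deposited table gives folds of 0.08 for MPP4 and 0.07 for CCNA1, against 0.11 for SOX4. The peptide-processing enzyme CPE had a log2 difference of -2.06 ± 0.14, the vesicle fusion protein VAMP7 -1.96 ± 0.07, and the cytokine IL11 -1.94 ± 0.13 (SE, n = 3 per group). The guidance factor SEMA3A followed with -1.93, LEF1, a transcription factor of the Wnt pathway, with -1.88, the protease inhibitor SERPINE2 with -1.88 and the neuropeptide NMU with -1.84. On the 3 SOX4 shRNA arrays CPE was above background on 2 and LEF1 on 1. Each of these had an adjusted p under 0.05 in limma with no overlap between the groups.

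**Figure D2:**
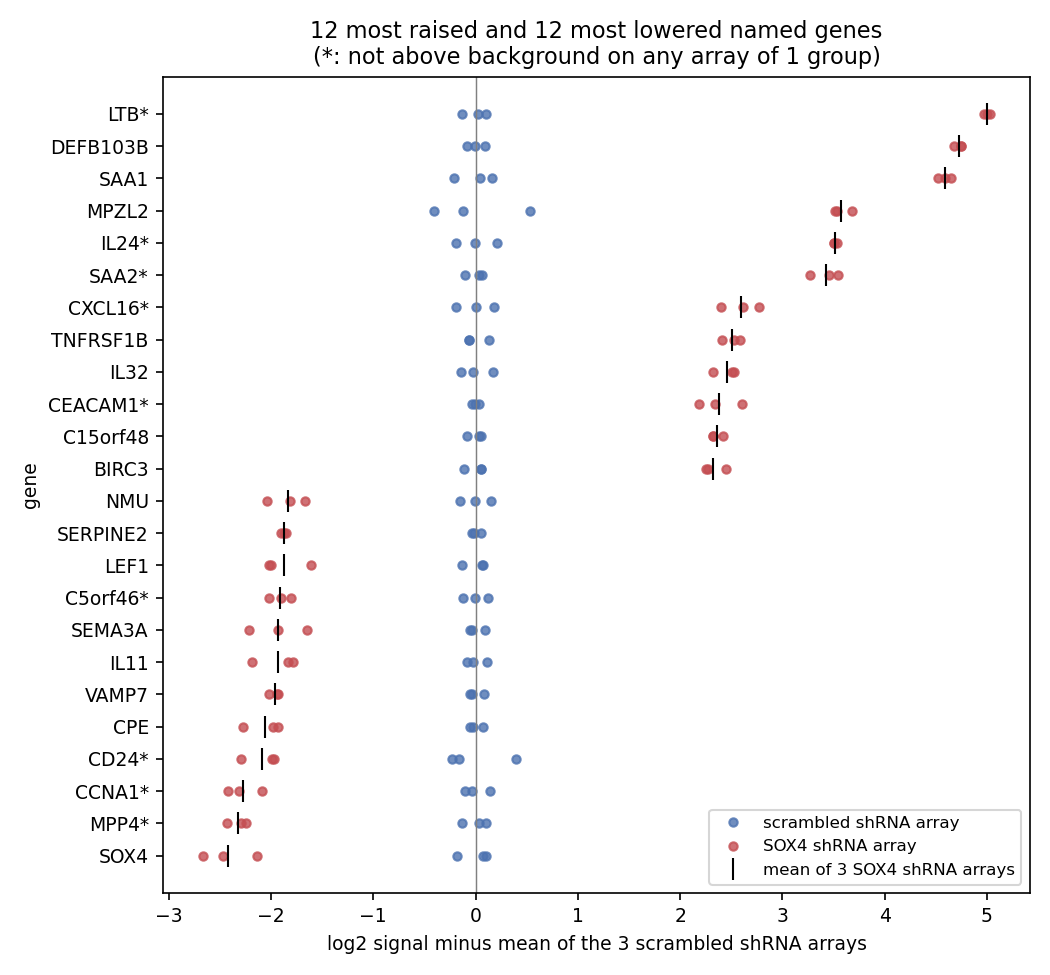
Log2 signal minus the mean of the 3 scrambled shRNA arrays (horizontal axis) for the 12 most raised and the 12 most lowered named genes; each point is 1 array, blue for scrambled and red for SOX4 shRNA, and the black tick is the mean of the 3 SOX4 shRNA arrays. SAA1 lies 4.59 above the scrambled mean and SOX4 lies at -2.43; for genes with an asterisk, not above background on any array of 1 group, the distance is not a measured fold.

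Genes of the NF-kB pathway and its cytokines rose together. Of 22 measured members of this list, 19 rose and 2 fell, with the same counts adjusted over the list alone, and 15 had a fitted rise of at least 2-fold, or 13 with bounds in place of fitted values. Besides IL24, IL32 and BIRC3, the inhibitor gene NFKBIA rose by 1.40 ± 0.06, IL6 by 1.94 ± 0.09, IL8 by 2.04 ± 0.08 and CSF2 by 1.94 ± 0.07 on the log2 scale (SE, n = 3 per group). The interleukin gene IL1A was at least 2.67-fold higher and the adhesion molecule ICAM1 at least 2.12-fold. The members that fell were IL11 and PTGS2, the inducible cyclooxygenase, which was at least 1.63-fold lower. The mean log2 difference of the list was 1.28, or 1.13 with its 7 members that were not above background in 1 group set at their bounds, and 0.75 with no background correction. The adjusted p over the 20 lists was 4.5e-18 in camera, and 0.012 with an estimated correlation.

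Interferon response genes also rose. Of 32 measured members, 24 rose and 1 fell, and adjusted over the list alone 26 rose. The antiviral gene RSAD2 was at least 3.02-fold higher, MX1 rose by 1.56 ± 0.08 and IFI27 by 1.13 ± 0.06 on the log2 scale (SE, n = 3 per group). Other members that rose included HLA-B by 1.04, the peptide transporter TAP1 by 0.79 and the immunoproteasome subunit PSMB9 by 0.90. The transcription factor IRF7 fell by 0.44 (-0.28 on another kept probe), a call lost with the authors' values (-0.35). The list mean was 0.57 with an adjusted p of 3.5e-16 in camera, and 0.027 with an estimated correlation.

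Hypoxia and glycolysis genes fell. Of 27 measured members, 19 fell and 2 rose, with the same counts adjusted over the list alone. ANGPTL4, a secreted lipase inhibitor, fell by 1.76 ± 0.09, the glycolytic regulator PFKFB4 by 1.08 ± 0.08 and ANKRD37 by 0.96 ± 0.10 on the log2 scale (SE, n = 3 per group). Of 3 kept probes of ANGPTL4 the smallest difference was -0.42, and its fold in the authors' deposited table was 0.57. The angiogenic factor VEGFA had a log2 difference of -0.56, and the enzymes GAPDH and ALDOA had -0.42 and -0.45. CA12 and DDIT4 rose, by 0.72 and 0.45. The list mean was -0.35 with an adjusted p of 1.3e-08 in camera, and 0.029 with an estimated correlation.

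**Figure D3:**
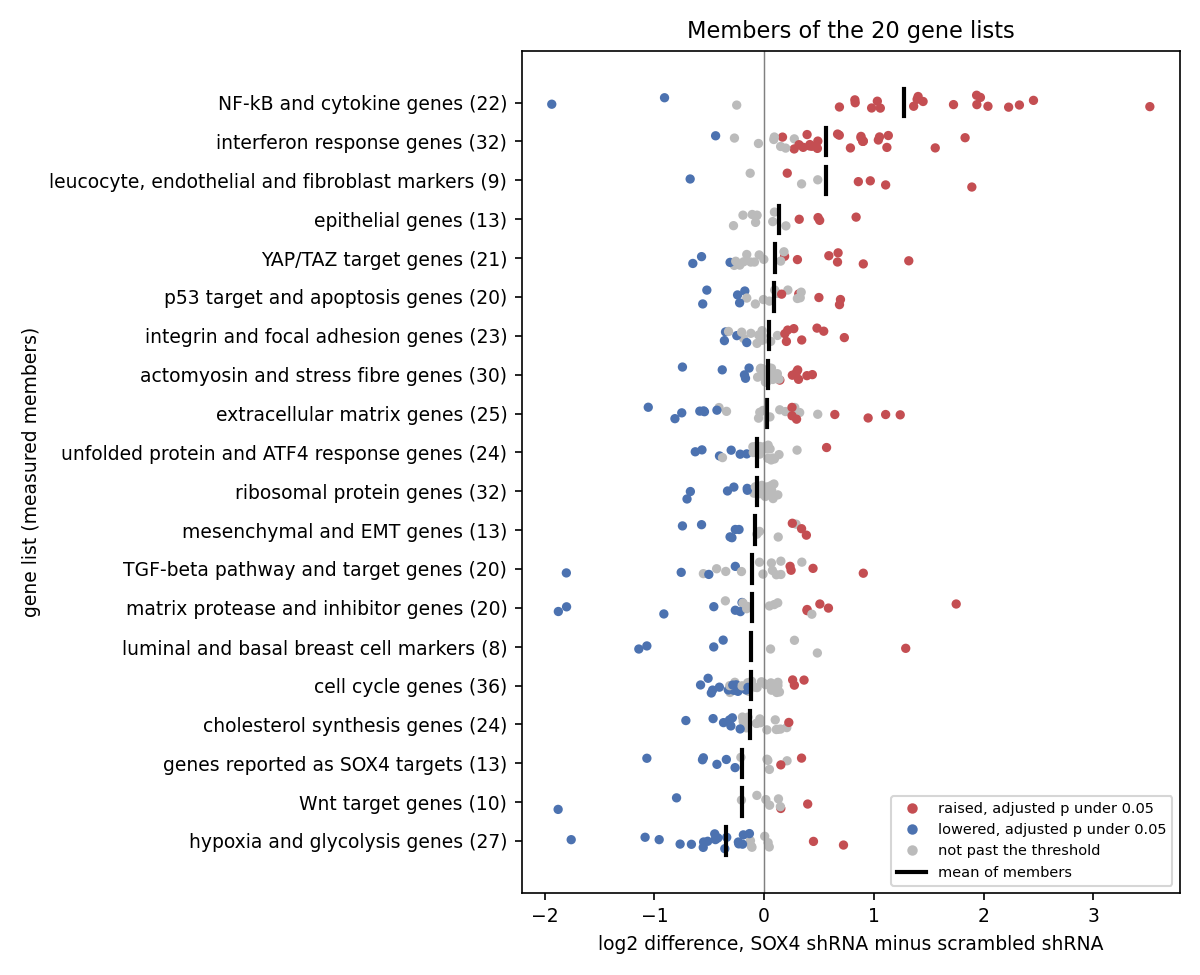
Log2 difference of SOX4 shRNA minus scrambled shRNA (horizontal axis) for each measured member of the 20 gene lists (vertical axis, with the number measured), red for raised and blue for lowered members at an adjusted p under 0.05, grey for the rest, and a black bar at each list's mean. The NF-kB list has the highest mean, 1.28, and the hypoxia and glycolysis list the lowest, -0.35.

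Neither the mesenchymal nor the epithelial list passed the threshold in camera. Both did in fry, which does not compare a list with other genes (adjusted p = 0.031 and 0.029). Of 13 measured mesenchymal genes, 6 fell and 3 rose, with a list mean of -0.09 and an adjusted p of 0.42 in camera. The smooth muscle actin ACTA2 fell by 0.74, the surface enzyme NT5E by 0.57 and the intermediate filament gene VIM by 0.23 ± 0.05, while S100A4 rose by 0.38, CDH11 by 0.34 and TAGLN by 0.26. N-cadherin, CDH2, had a log2 difference of 0.29 ± 0.20 (SE, n = 3 per group) and SNAI2 one of 0.13 ± 0.07, neither past the threshold (adjusted p = 0.28 and 0.20, limma). CDH2 had 0.12 without SOX4 shRNA replicate 3 and 0.44 without scrambled array 2b. E-cadherin, CDH1, and fibronectin, FN1, were not above background on any array, and ZEB1 was above it on 1 array of each group. Of 13 measured epithelial genes, 4 rose and 0 fell, and adjusted over the list alone 5 rose: the tetraspan gene MAL2 rose by 0.84, the junction protein JUP by 0.51 and EPCAM by 0.49. The list mean was 0.13 and the adjusted p 0.42 in camera. With the authors' values JUP (0.14) and TAGLN (0.27) did not pass the threshold, nor did TAGLN without SOX4 shRNA replicate 1 (0.21). Without SOX4 shRNA replicate 3, 1 epithelial gene fell. With the authors' values 2 epithelial genes rose and 0 fell, and the list median was -0.065 there, against 0.078 in the main setting.

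Contractile, adhesion and mechanical signalling genes moved in both directions. Of 30 measured actomyosin genes, 7 rose and 5 fell (camera adjusted p = 0.46). The kinase MYLK and the light chain MYL9 rose by 0.44 and 0.39, and TAGLN2 fell by 0.38. MYH9, the heavy chain of non-muscle myosin, had a log2 difference of 0.06 ± 0.06 (SE, n = 3 per group) and its sign changed between settings (-0.017 without scrambled replicate 1). Of 23 measured integrin and focal adhesion genes, 8 rose, led by ITGB4 with 0.73 (0.45 on its other kept probe) and ITGA6 with 0.54, and 4 fell, led by TGFB1I1 with -0.36 (camera adjusted p = 0.58; list mean 0.04, median -0.02). That mean was 0.023 without SOX4 shRNA replicate 1 and 0.071 without scrambled array 2b. Of 21 measured YAP/TAZ targets, 7 rose, among them NUAK2 (above background on 1 scrambled array) with 1.32 and TGFB2 with 0.90, and 3 fell, among them CTGF with -0.65 (camera adjusted p = 0.58; list mean 0.10, median -0.05). In the TGF-beta list 4 of 20 measured members rose and 4 fell, and PMEPA1, a feedback inhibitor of that pathway, fell by 1.80 ± 0.08 (SE, n = 3 per group; smallest difference of its 3 kept probes -0.75; camera adjusted p of the list = 0.73; list mean -0.11, median 0.03). Counts adjusted over the list alone were the same for these lists and for the mesenchymal one. The calls of MYLK (0.73) and TGFB1I1 (-0.51) were lost with the authors' values. In those values 4 integrin and focal adhesion genes rose and 1 fell, and 5 actomyosin genes rose and 3 fell. With 1 array left out, 2 actomyosin genes fell without scrambled 1 or SOX4 shRNA 2 and 3 without scrambled 2a or SOX4 shRNA 1, and 2 TGF-beta genes rose without SOX4 shRNA 3. The list medians near 0 moved as well, to 0.00021 for integrins and -0.00044 for YAP/TAZ targets without SOX4 shRNA 2, to -0.090 for YAP/TAZ targets without SOX4 shRNA 3, and to -0.040 and -0.031 for the TGF-beta list without scrambled 2b and 2a.

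Matrix genes and proteases likewise split. Of 25 measured extracellular matrix genes, 7 rose and 7 fell, and adjusted over the list alone 10 rose. The collagens COL13A1 and COL7A1 fell by 1.06 and 0.81 (camera adjusted p = 0.89; list mean 0.03, with its sign depending on the setting). Of 20 measured matrix proteases and inhibitors, 5 rose and 7 fell, or 7 and 10 adjusted over the list alone. The gelatinase MMP9 was at least 1.90-fold higher, the collagenase MMP1, above background on 2 SOX4 shRNA arrays, fell by 1.80, and SERPINE2 fell as given above (camera adjusted p = 0.58).

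Of 13 measured genes reported elsewhere as SOX4 targets, 6 fell and 2 rose, with the same counts adjusted over the list alone. The receptor EGFR fell by 1.07 ± 0.09, the tubulin TUBB3 by 0.56 ± 0.06 and the histone methyltransferase EZH2 by 0.34 ± 0.08 on the log2 scale (SE, n = 3 per group), while DICER1 and CCND1 rose by 0.34 and 0.15. The list did not pass the threshold (mean -0.20, camera adjusted p = 0.11). Of 36 measured cell cycle genes, 13 fell and 3 rose, or 13 and 4 adjusted over the list alone. Those that fell included FOXM1, CDC25C and CENPF, with log2 differences of -0.58, -0.51 and -0.48, and those that rose were CDC25A, MCM6 and CCNE2, with 0.36, 0.28 and 0.26. The list lay close to the threshold (mean -0.12, camera adjusted p = 0.058) and passed it under several other settings, but not with an estimated correlation (adjusted p = 0.49 with an estimated correlation). EGFR had -0.61 on its other kept probe. With the authors' values EGFR fell by 0.62, and DICER1 (0.39) and CCNE2 (0.26) did not pass the threshold. The call of CCND1 was lost without scrambled array 2b (0.13) or SOX4 shRNA replicate 1 (0.14).

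The cholesterol, unfolded protein, p53, Wnt and ribosomal lists did not pass the threshold in camera either. Of 24 measured cholesterol synthesis genes, 7 fell, led by TM7SF2 with -0.71 (camera adjusted p = 0.11). Of 24 measured unfolded protein and ATF4 response genes, 6 fell, led by the chaperone HSPA5 with -0.63, and ERN1 rose by 0.57, a call lost with the authors' values at 0.54 (camera adjusted p = 0.49). Of 20 measured p53 targets and apoptosis genes, 5 rose, led by PHLDA3 with 0.70, and 5 fell, led by TP53I3 with -0.56, which was 0.25 in the authors' values (camera adjusted p = 0.46). Adjusted over the list alone, 7 of these rose and 6 fell. Of 10 measured Wnt targets, LEF1 and AXIN2 fell by 1.88 and 0.80, and MYC and CCND1 rose by 0.40 and 0.15 (camera adjusted p = 0.82; list mean -0.21, median 0.03). Of 32 measured ribosomal protein genes, 6 fell and 0 rose, led by RPL37 with -0.70 (camera adjusted p = 0.42). Counts adjusted over the list alone were the same for these lists except the p53 one. Of the p53 list, 3 members rose and 3 fell without scrambled 1, scrambled 2a or SOX4 shRNA 2, and 3 fell without scrambled 2b. Of the unfolded protein list, 3 fell without scrambled 1 or SOX4 shRNA 2, and 2 rose without scrambled 1. Without scrambled 2b, 1 Wnt target rose, and the Wnt median was -0.0080 without scrambled 2a. Without scrambled 2b or SOX4 shRNA 3, 1 ribosomal gene rose.

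Some markers of other cell types were undetected and others were detected. The leucocyte genes PTPRC and CD3D, the endothelial genes CDH5, VWF and KDR and the fibroblast genes PDGFRA, DCN and POSTN were not above background on any array. LYZ was above it on 3 scrambled and 2 SOX4 shRNA arrays, PECAM1 on 1 and 2, and COL1A1 on 1 scrambled array only. LUM was above it on no scrambled array and on 3 SOX4 shRNA arrays (log2 difference 0.49, adjusted p = 0.069, limma). In the combined leucocyte, endothelial and fibroblast list, 5 of 9 measured members rose and 1 fell, or 6 and 1 adjusted over the list alone. CD14, a lipopolysaccharide receptor, rose by 1.89 ± 0.09 and CD74, the class II invariant chain, by 0.97 ± 0.08 on the log2 scale (SE, n = 3 per group), and both were detected on every scrambled array. Another kept probe of CD74 gave 0.43. PDGFRB was at least 1.34-fold lower, a call lost without scrambled array 2a (-0.53) or SOX4 shRNA replicate 1 (-0.54). COL1A2 had a log2 difference of 1.11 on its representing probe and 0.03 when the probe detected on all 6 arrays was used. It had 0.05, 0.11 and -0.08 without SOX4 shRNA replicate 1, 2 or 3, as another probe then stood for it. The list mean was 0.56 with an adjusted p of 4.8e-04 in camera, a call lost with an estimated correlation (adjusted p = 0.12 with an estimated correlation). Of 8 measured luminal and basal breast markers, TFF3 rose by 1.29 and 4 fell, among them SPDEF by 1.14 (camera adjusted p = 0.21); adjusted over the list alone 2 rose and 4 fell, and 2 rose over all genes without scrambled 2a. ESR1, PGR, KRT5 and KRT14 were not above background on any array.

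The authors' deposited table of group means lists SOX4 at a fold of 0.11, with log2 means of 7.75 and 4.59. A fold of at least 2 is given for 457 genes and one of at most 0.5 for 446, among 22277 in the authors' deposited table. Across 12067 matched genes, which are not independent replicates, log2 differences from the authors' values and from the normalization used here correlated at 0.928, with a slope of 1.20 for the authors' values on those used here.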

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

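Alternatives were fixed before the data were examined, except the replicate block in the authors' values, which was chosen after seeing the data. The NF-kB, interferon and hypoxia lists kept their direction and call in each setting run for lists, which leaves out the test of every kept probe. The SOX4 transcript level did so in each setting that gave it a value, between -3.22 with the authors' values and -1.23 with no background correction; with detection required on all 6 arrays it was not tested. The count of 3807 changed genes became 280 with a required fitted 2-fold change (162 raised, 118 lowered), and lay between 3147 and 3288 with 1 array left out. It was 2852 with the authors' values (2681 of them also called in the main setting), 2892 without an intensity trend and 3042 without a detection filter. The slide as a block was not run, since no slide is named. The block for the replicate number gave 3841 or 3836 changed genes, depending on which of the 2 columns with the same heading is replicate 2, and 2665 with the authors' values. Samples that share a number did not deviate together (r = 0.016, -0.0011 and -0.023 in the authors' values), which does not show what else they share.

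The cause of the following moves was not tested, except for COL1A2, where another probe came to stand for the gene. The gene MYH9 turned to -0.00188 with the authors' values, with or without the replicate block, and to -0.00183 with the mean of probes. TP53I3 turned to 0.25 with the authors' values, with or without the block. The extracellular matrix list turned to -0.00435 with no background correction, -0.054 with detection on all 6 arrays and -0.010 with the mean of probes. The luminal and basal list turned to 0.013 with no detection filter and passed the threshold at -0.28 with detection on all 6 arrays. The cell cycle list passed it at -0.12 with cyclic loess, with no detection filter and with the mean of probes, and at -0.14 with the authors' values, with or without the block. With no detection filter the SOX4 target list passed it at -0.15 and the cholesterol list at -0.14. With an estimated correlation in the main setting the cell cycle, SOX4 target, cholesterol, and luminal and basal lists each had an adjusted p of 0.49. The leucocyte, endothelial and fibroblast list, at 0.56, no longer passed with an estimated correlation. With 1 array left out, MYH9 lay between -0.017 (without scrambled 1) and 0.13, COL1A2 between -0.082 (without SOX4 shRNA 3) and 1.29, the extracellular matrix list between -0.027 and 0.050, the cell cycle list between -0.14 and -0.11 (past the threshold without scrambled 2b or SOX4 shRNA 3) and the cholesterol list between -0.15 and -0.0923 (past it without scrambled 1).

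Fry, which asks only whether a list's genes move on balance one way and not whether they move more than others, passed the threshold for 11 further lists. Their means are those of the main setting: mesenchymal -0.086, epithelial 0.13, actomyosin 0.039, SOX4 targets -0.20, proteases -0.11, cell cycle -0.12, p53 0.092, cholesterol -0.12, Wnt -0.21, ribosomal -0.068, and luminal and basal -0.12. Of 111 genes named by the rule and past the threshold, 17 lost their call and 1 reversed with the authors' values, 22 lost it with the replicate block there, and between 1 and 7 lost it with 1 array left out. With no background correction 0 lost it, but 50 were smaller by over 1.5 times. Signal over background limits what can be said of dim genes: 33.2% of the probes were kept.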

Other observations

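All tests on gene families, neighbouring genes and list explanations below were chosen after the results were seen, except the counts of splits. The comparison of parts of a chromosome was set before its own values were seen. It used a chromosome picked from these results, and replaced a first dosage test whose result had been seen. A scan of 313 groups of genes that share a symbol stem, chosen after the data were seen, gave 6 with an adjusted p under 0.05 in camera at the preset correlation, and 0 of these passed with an estimated correlation. The cancer-testis genes of the SPANX family all fell, with log2 differences from -1.67 for SPANXE to -1.31 for SPANXB2 (6 of 6 members; mean -1.49; adjusted p = 1.8e-14, and 0.98 with an estimated correlation). Their sequences are near copies of each other, so the probes are not separate measurements. The class II antigen presentation genes rose, from 0.33 for HLA-DRB3 to 2.02 for HLA-DPA1 (7 of 7 members; mean 1.01; adjusted p = 2.5e-09, and 0.98 with an estimated correlation). Whether probes of related genes in this family and those below are separate measurements was not tested. Of 6 metallothionein genes 5 fell, MT2A by 0.58 and MT1G by 0.83, and MT1F rose by 0.44 (mean -0.36; adjusted p = 0.0081, and 0.99 with an estimated correlation). Of 22 histone genes 8 fell and 0 rose, with a mean of -0.27 (adjusted p = 0.024, and 0.99 with an estimated correlation).

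The rise of NF-kB and cytokine genes was weighed against technical explanations. Admixed leucocytes would bring their abundant transcripts, but of 9 such transcripts not detected on any scrambled array, among them PTPRC, 0 were detected on every SOX4 shRNA array. Among the 9 of 20 that were tested, 4 fell, LAPTM5 by 0.42 and LSP1 by 0.59, and 3 rose, LCP1 by 0.87; CD14, CD74 and the class II genes also rose, and were detected with the scrambled hairpin too. Dim probes as the whole cause are argued against by the list mean of 1.27 among genes detected on all 6 arrays. That setting keeps the same normalization, so it cannot speak to the normalization. With cyclic loess the list median was 1.405, with 19 members raised and 2 lowered. In the authors' values the list median was 1.931, with 18 raised and 2 lowered. The direction thus held under these other normalizations. The size depends on the processing, with a mean of 0.75 and a median of 0.53 with no background correction, against 1.28 and 1.40. An interferon response to a double-stranded RNA hairpin stays open: the interferon list mean was 0.57, but the NF-kB list rose too (1.28), both groups carry a hairpin, and there is 1 SOX4 hairpin and no untransduced sample. An off-target effect of that hairpin and a response to loss of SOX4, the difference the design names, cannot be told apart here and stay untested. Nor can other differences between the transduced populations, such as the shifts of neighbouring genes described below, be told apart from these. That the rise follows from SOX4 loss is therefore only a hypothesis.

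The fall of hypoxia and glycolysis genes was not matched by other genes of like brightness. Its median, -0.34, lay at percentile 0 of 10000 random lists matched on mean signal, whose lowest median was -0.14. These lists were drawn from quantile-normalized values, which holds their medians near 0. The draws therefore do not decide whether bright signals were compressed before normalization. The fall was not confined to glycolysis. Of the 10 members outside the glycolytic enzymes and the glucose transporter, 5 were lowered, among them ANGPTL4, ANKRD37 and VEGFA, and 2 were raised. Whether these 10 fell as a set stays open: their mean was -0.34, but they went in both directions, with an SD of 0.71 between members. The 17 others had a mean of -0.35, and 14 of them were lowered and 0 raised. A difference in culture density or oxygen between the groups was not recorded in the labels and was not tested, and loss of SOX4 stays open beside it. Whether the shifts of neighbouring genes described next contribute to this fall was not tested.

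Neighbouring genes tended to shift together, which may reflect gene dosage that differs between the transduced populations. On the chromosome that carries LAMA3 and MALT1, 72.5% of 138 tested genes lay above 0, against 48.7% of all 10200 placed genes, with a median of 0.19 (between 0.17 and 0.22 on the 3 SOX4 shRNA arrays; 0.20 in the authors' values). Its p over 10000 random draws of genes was 1e-04, the smallest they can give, with an adjusted p of 4.6e-04 over 23 chromosomes. Of these 12 passed, 7 above and 5 below the median of all genes. The lowest was the one with CCDC77 at -0.12 over 516 genes, 32.6% above 0. These draws treat genes as independent. For the chromosome with LAMA3 and MALT1, the largest median in the other splits of the arrays was 0.08 in size. Those splits mix the groups, so this does not show a noise level. The first 69 and last 69 genes of that chromosome had medians of 0.13 and 0.21. It was picked for the largest median of these same genes, so this decides nothing and dosage stays an open hypothesis. DNA was not measured. Families of related genes as the whole cause are argued against: with 1 gene per symbol stem the lowest median over 25 neighbouring genes was -0.39 (LRRC47 to PGD; 0 of 1000 shuffles as low), and -0.38 at another stretch in the authors' values (PA2G4 to DCTN2; 3 of 1000).

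Splits of the 6 arrays into 3 and 3 number 10, too few for a share under 0.05. Every split other than the real one has arrays of both groups on either side, which shrinks its differences and widens its spread. Low counts and means in those splits are therefore built in and do not show a noise level. The real split gave 3807 changed genes, 1891 raised and 1916 lowered, and the highest count in the other splits was 0 for each; only the real split (1 of 10) gave as many. For the list means, the real split and the highest of the others gave 1.28 and 0.45 for NF-kB genes, 0.57 and 0.22 for interferon genes, 0.35 and 0.16 in size for hypoxia genes, and 0.56 and 0.25 for the leucocyte, endothelial and fibroblast list.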
